A study of Mus musculus with 24 samples.

How the data were processed

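RNA from mouse hippocampus was sequenced in 24 libraries that the labels place in 8 groups of 3. The mice were C57BL/6 x FVB hybrids. The labels give the genotype hMECP2-GFP (called hGFP here) for 1 group and hMECP2-GFP;hMECP2 (called hDup here, 2 human MECP2 alleles) for the other 7. An antisense oligonucleotide (ASO) is a short modified nucleic acid that pairs with a chosen RNA and can lead to its cleavage. The hGFP group and 1 hDup group had a control ASO, and 6 hDup groups had a MECP2 ASO and were harvested 1, 2, 5, 8, 12 or 16 weeks later. The labels give an age of 10 weeks for both control groups and for the 1-week group, and of 11, 14, 17, 21 and 25 weeks for the later groups, so time after the MECP2 ASO and age rise together.

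Per the labels, the authors trimmed reads with Trimmomatic 0.36, aligned them with STAR 2.6.0a to mm10 and had STAR count reads per gene. The deposited values are counts, that is, whole reads per gene without normalisation, in a column for unstranded reads and a column for each strand. The totals of both strand columns were nearly equal in every library (ratio 1.004 to 1.007), below the ratio of 5 set as the condition for a stranded column, so the unstranded column was used. The stranded columns were not run as an alternative. Each file holds 54233 genes: 54232 mouse genes and an added entry named for human MECP2. The annotation release was not stated. Of the mouse gene IDs, 54079 matched GENCODE M21 (GRCm38), which gave symbols and coordinates. The added human entry has no coordinates in the files, and how reads shared by the human and the mouse gene were assigned was not stated. The 4 totals of reads that were not counted at a gene were left out of all gene tests.

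Reads counted at genes ran from 11.6 to 23.03 M per library (median 18.1 M). CPM are counts over the gene reads of a library, scaled to a sum of 1e+06. For human MECP2, the 95% exact binomial (Clopper-Pearson) interval of a single library reached 2.08% to 5.50% to either side of its value. Intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

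Genes with low counts were removed with filterByExpr on the groups, which left 19140. Fold changes and tests came from edgeR 4.0.16 (with limma 3.58.1 in R 4.3.3): TMM normalisation, a quasi-likelihood fit with 1 mean per group over all 24 libraries, and F tests with Benjamini-Hochberg adjustment at 0.05. The comparisons were hDup control against hGFP control, each time of MECP2 ASO against hDup control and against hGFP control, and a test of any difference over the 6 times. These comparisons, the alternatives not marked as added, the gene lists and the rule for named genes were fixed before the data were examined. The rule names Mecp2 in each comparison, and by log2 fold change up to 12 genes in each direction for the genotype comparison (6 for a time against hDup control, 3 for a time against hGFP control), among genes with an adjusted p under 0.05, a mean log2 CPM of at least 1 and no overlap of the libraries. It also names the 6 genes of smallest p over time with that mean, and up to 4 members of smallest p in each list described. No gene had an adjusted p under 0.05, so other genes named were chosen after their values were seen.

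A total of 37 gene lists (cell type markers, receptors and channels, stress, immune and metabolic pathways, genes reported as sensitive to MeCP2) were tested with camera at its preset correlation between genes, adjusted over the lists of a comparison. Beside it stand camera with an estimated correlation and fry, which asks whether a list's genes move on balance in 1 direction. A list of sex chromosome genes was used only to describe libraries. Members were also counted after adjustment over the list alone, uncorrected across lists and comparisons, so some may pass by chance. Long genes (span over 100 kb, 2417 genes) were compared with the 16705 others that had coordinates. Single values of 3 against 3 libraries were compared by two-sided exact permutation tests, whose smallest possible p is 0.1. Pearson correlations of fold changes are across genes, which are not independent replicates, and stand beside values from simulated groups without changes.

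The procedure was tested on simulated data with 3 libraries per group: for the genotype comparison, edgeR recovered 14% of genes changed 1.25-fold, 50% of those changed 1.5-fold, 84% of those changed 2-fold and all of those changed 4-fold. The alternatives were DESeq2 1.42.0, DESeq2 size factors in edgeR, no filter on low counts, a fit of only the groups compared, a term for the replicate number, a minimum fold of 1.2 (glmTreat), spans over 50 and 200 kb for long genes, and leaving out each library in turn. After the data were seen, further alternatives were added: a term for libraries with Y-linked reads, a term for the level of choroid plexus markers, leaving out 8-week library 2 from every comparison, and lists of the 100 genes of smallest p in the genotype comparison. Libraries are numbered as the replicates in the labels. The labels do not say whether the libraries of a group come from separate animals, so p-values measure the spread between libraries only. No library was removed.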

Results

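The data were 24 hippocampal RNA libraries in 8 labelled groups of 3: hGFP control, hDup control, and hDup mice 1, 2, 5, 8, 12 and 16 weeks after a MECP2 ASO. The libraries held 17.0 to 34.99 M reads, of which 11.6 to 23.03 M were counted at genes (group means 20.4 M for hGFP control, 18.4 for hDup control, and 20.8, 17.0, 14.1, 15.9, 18.2 and 18.2 in order of time). Reads were seen at 24726 to 27765 genes per library. Unmapped reads made up 9.48% to 18.5% of a library, reads outside genes 9.27% to 10.9%, and reads with several alignments 3.22% to 4.76%.

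Human MECP2, the transcript of the transgenes and the target of the MECP2 ASO, did not separate the labelled groups. Its level was 267 ± 150 CPM in the group labelled hGFP control and 323 ± 103 in the group labelled hDup control (mean ± SD, n = 3 each). In the groups labelled 1, 2, 5, 8, 12 and 16 weeks it was 211 ± 8.68, 393 ± 85.2, 206 ± 118, 294 ± 161, 335 ± 102 and 360 ± 99.5 CPM. The 3 libraries labelled hGFP control stood at 96.6, 380 and 325 CPM and those labelled hDup control at 384, 204 and 381, where 1 and 2 alleles are labelled. At 1 week the libraries stood at 215, 202 and 218 CPM, at 2 weeks at 438, 295 and 446, and at 5 weeks at 328, 197 and 91.6. The libraries labelled 8 weeks held 377, 108 and 396 CPM, those labelled 12 weeks 387, 218 and 402, and those labelled 16 weeks 439, 248 and 392. The highest library of a group was 1.08 (1 week) to 3.93 (hGFP control) times the lowest, where the counting error of a library was at most 5.50%. At 1 week the libraries were thus close to each other, while in the other 7 groups the ratio was 1.513 or more. Of the variance in log2 human MECP2, 71.9% lay within groups, where random labels give 69.6% (permutation p = 0.528 over 8 groups). The log2 difference of hDup control from hGFP control was 0.44 (exact two-sided permutation p = 0.5, smallest possible 0.1), of 1 week from hDup control −0.55 (exact p = 0.3) and of 5 weeks from hDup control −0.78 (exact p = 0.2). Exact p for 2, 8, 12 and 16 weeks against hDup control was 0.5, 0.8, 0.5 and 0.5, and against hGFP control it was 1, 0.3, 0.6, 0.6, 0.5 and 0.5 in order of time. In edgeR the log2 fold change of hDup control over hGFP control was 0.27 (SE 0.45, adjusted p = 0.969), and it was −0.13 without hGFP control library 1. The comparisons below therefore refer to groups as labelled.

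**Figure D1:**
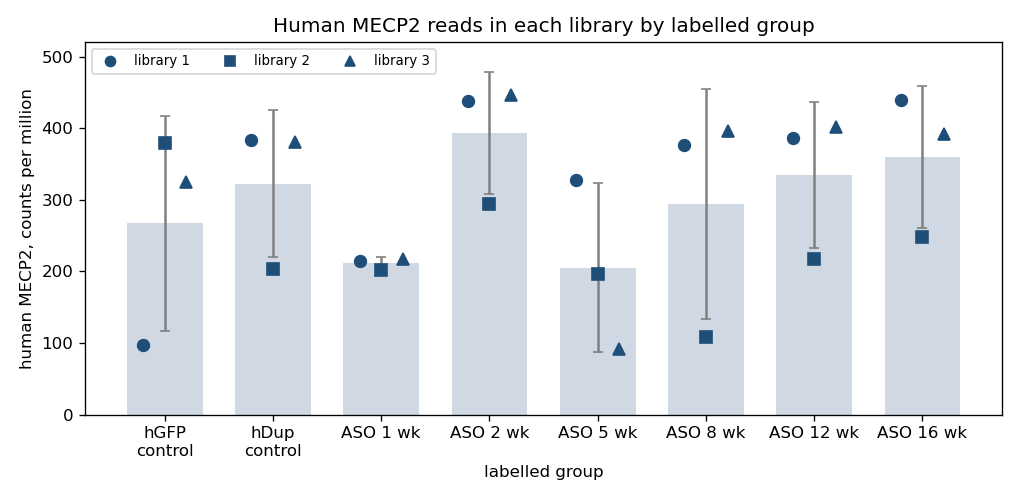
Human MECP2 in CPM (vertical axis) for each library of the 8 labelled groups (horizontal axis), with bars for the group mean and lines for the SD. Libraries labelled hGFP control span 96.6 to 380 and libraries labelled hDup control span 204 to 384, so the labelled groups overlap.

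Libraries also differed in ways the labels do not name. Reads of the Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y were present in 7 libraries: library 1 of 1 week, all 3 of 2 weeks, libraries 1 and 2 of 5 weeks, and library 1 of 16 weeks. Ddx3y (ENSMUSG00000069045.11, chromosome Y, 1260771 to 1286629) stood at 54.6 to 65.5 CPM in these and at 0.284 or less in the other 17, including all control libraries. Xist, the RNA that coats the inactive X chromosome (ENSMUSG00000086503.3, chromosome X, 103460366 to 103483254), stood at 0.884 to 3.38 CPM in the 7 and at 501 to 675 in the others except 8-week library 2, which had 63.5. That library also held the highest Tcf7l2 (22.7 CPM) and Prkcd (57.5 CPM), genes abundant in thalamus, and the highest Hba-a1 (69.0 CPM), a haemoglobin gene. Ttr, the transthyretin made by choroid plexus, ranged from 27.2 to 5355 CPM. The pituitary hormone genes Prl and Gh reached 81.7 and 69.2 CPM in hGFP control library 1. No pair of the 24 libraries was a repeat of another, and the first principal components held 17.8% and 11.4% of the variance.

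The comparison of hDup control with hGFP control asks which hippocampal genes differ with a second MECP2 allele. Markers of choroid plexus, the epithelium that makes cerebrospinal fluid, were lower in the group labelled hDup control: all 18 were lower, with a median log2 fold change of −1.30 (camera adjusted p = 7.58e-11; adjusted p = 0.775 with an estimated correlation), and −0.80 without hDup control library 1, still called. Among them Sostdc1, a secreted antagonist of BMP signalling, stood at 8.31 ± 5.64 against 21.1 ± 7.23 CPM (SD, n = 3 each). Markers of mural cells and fibroblasts were lower in 11 of 15 (median −0.49, camera adjusted p = 3.31e-05; adjusted p = 0.746 with an estimated correlation), and Ogn, a small proteoglycan of connective tissue, was the 1 member past the threshold adjusted over the list alone (−0.98, SE 0.27, list adjusted p = 0.0207; 0 over all genes). Oligodendrocyte markers were higher in 17 of 18 (median 0.26, camera adjusted p = 8.27e-06; adjusted p = 0.843 with an estimated correlation), among them Myrf, a transcription factor of myelination (84.6 ± 17.0 against 63.9 ± 13.6 CPM). This call ended without hDup control library 1 (median 0.14) or hGFP control library 1 (0.095), and the median was 0.17 and 0.444 without hDup control library 2 and 3. Spp1 (osteopontin) was the 1 microglial activation gene that passed adjusted over the list alone (log2 fold change −1.35, SE 0.40, list adjusted p = 0.0485).

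For this pair edgeR called 0 of 19140 genes, 846 had an unadjusted p under 0.05 (957 by chance; 1291 without 8-week library 2), and DESeq2 called 1. That gene was the Y-linked Eif2s3y, which stood at 0.113 CPM or less in these 6 libraries. Without hGFP control library 1, edgeR called 1 gene, Ide, the insulin-degrading enzyme (log2 fold change −0.71). The libraries of both groups did not overlap for 12.1% of genes, where chance gives 10%. The gene of smallest p was Cdkn1c, an imprinted inhibitor of the cell cycle (ENSMUSG00000037664.13, chromosome 7, 143458339 to 143461050), at 2.82 ± 0.494 against 6.83 ± 1.74 CPM (log2 fold change −1.28, SE 0.28, adjusted p = 0.954), named after its values were seen. Camera called 8 of 37 lists, 4 higher and 4 lower, and 2 of these calls held when any 1 library was left out. The count was 5 without hGFP control library 1, 4 without its library 2, 14 without its library 3, 5 without hDup control library 1 and 13 without its library 2.

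The group labelled 1 week is the MECP2 ASO group of the same age as the controls. Genes of cholesterol synthesis and uptake were lower than in hDup control in 18 of 19 (median −0.17, camera adjusted p = 5.88e-14; adjusted p = 0.0581 with an estimated correlation; fry adjusted p = 0.175). Among them were Ldlr, the receptor for low-density lipoprotein (21.7 ± 0.903 against 29.2 ± 5.71 CPM, SD, n = 3 each), Hmgcr, the rate-limiting enzyme of the pathway (84.3 ± 4.99 against 103 ± 13.7 CPM), and Fdft1 and Sqle, enzymes of sterol synthesis. None of the 19 passed over all genes or adjusted over the list alone (smallest list adjusted p = 0.0532 for Ldlr). Blood markers were higher in all 6 (median 0.86, camera adjusted p = 4.46e-07; adjusted p = 0.238 with an estimated correlation), and mural cell and fibroblast markers in 13 of 15 (median 0.38, camera adjusted p = 4.46e-07; adjusted p = 0.238 with an estimated correlation). These 3 calls held without any 1 library, though the mural cell and fibroblast median was 0.621 without 1-week library 1 and 0.197 without its library 2. Interferon response genes were higher in 17 of 19 (median 0.17, camera adjusted p = 1.66e-05; adjusted p = 0.304 with an estimated correlation), but not past the threshold without 1-week library 2 (median 0.06), while the median was 0.466 without hDup control library 2 and 0.265 without 1-week library 3. Choroid plexus markers were higher as well, in all 18 (median 0.756, camera adjusted p = 0.00086; adjusted p = 0.62 with an estimated correlation), a call that ended without hDup control library 1 (0.242), 1-week library 1 (0.691) or 1-week library 2 (0.063).

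At 1 week against hDup control edgeR called 0 genes, 416 had an unadjusted p under 0.05 (746 without 1-week library 1), and DESeq2 called 0. Libraries did not overlap for 7.31% of genes, where chance gives 10%. Human MECP2 had a log2 fold change of −0.61 (SE 0.46, adjusted p = 1) and mouse Mecp2 of −0.03 (SE 0.28). The sign of the mouse value turned without hDup control library 2 (0.07) or 1-week library 2 (0.16). Camera called 16 lists, 9 higher and 7 lower, and 7 without 1-week library 2. Library 1 of this group had Y-linked reads and the controls had none.

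At 2 weeks choroid plexus markers were far lower than in hDup control, in all 18 members (median −2.82, camera adjusted p = 2.1e-18; adjusted p = 0.339 with an estimated correlation; 16 members adjusted over the list alone, 0 over all genes). Ttr, the carrier of thyroid hormone, stood at 91.2 ± 70.7 against 979 ± 846 CPM (SD, n = 3 each), and Otx2, a transcription factor of choroid plexus, at 1.56 ± 0.867 against 7.56 ± 5.37. Ependymal markers were lower in all 11 (median −0.65, camera adjusted p = 8.66e-07; adjusted p = 0.339 with an estimated correlation; −0.38 without 2-week library 1). Potassium channel genes were higher in 20 of 22 (median 0.10, camera adjusted p = 0.000183; adjusted p = 0.339 with an estimated correlation), among them Kcnq3, which carries the M current (231 ± 20.5 against 197 ± 7.09 CPM). Adjusted over the list alone, Creb1, a transcription factor of activity-dependent expression (log2 fold change 0.38, SE 0.10), and Grin2a, an NMDA receptor subunit (0.37, SE 0.10), passed among genes reported as sensitive to MeCP2 (list adjusted p = 0.0136 for each). So did Trpc6, a cation channel, among dentate granule markers (0.44, SE 0.13, list adjusted p = 0.0432).

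All 3 libraries of the group labelled 2 weeks had Y-linked reads and no hDup control library did, so sex of the animals goes with this comparison. With a term for Y-linked reads, estimated from the groups that hold both kinds, the ependymal call (median −0.37) and the potassium channel call (0.02) ended, while the choroid plexus median was −2.39 and still called. The term took the number of lists called from 16 (7 higher, 9 lower) to 5, and that number was 9 without hDup control library 2 or 2-week library 1. A choroid plexus term also ended the ependymal call (median −0.19). In edgeR 0 genes were called, 1140 had an unadjusted p under 0.05 (612 with the Y-linked term, 737 without 2-week library 1), and libraries did not overlap for 13.9% of genes (10% by chance). DESeq2 called 2 genes, Capn6 (log2 fold change −1.38) and Mid1 (−1.61), both on the X chromosome, and edgeR on only these groups called 10. For human MECP2 the log2 fold change was 0.28 (SE 0.45, adjusted p = 0.956; −0.36 with the Y-linked term) and that of mouse Mecp2 was 0.52 (SE 0.28, adjusted p = 0.833).

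**Figure D2:**
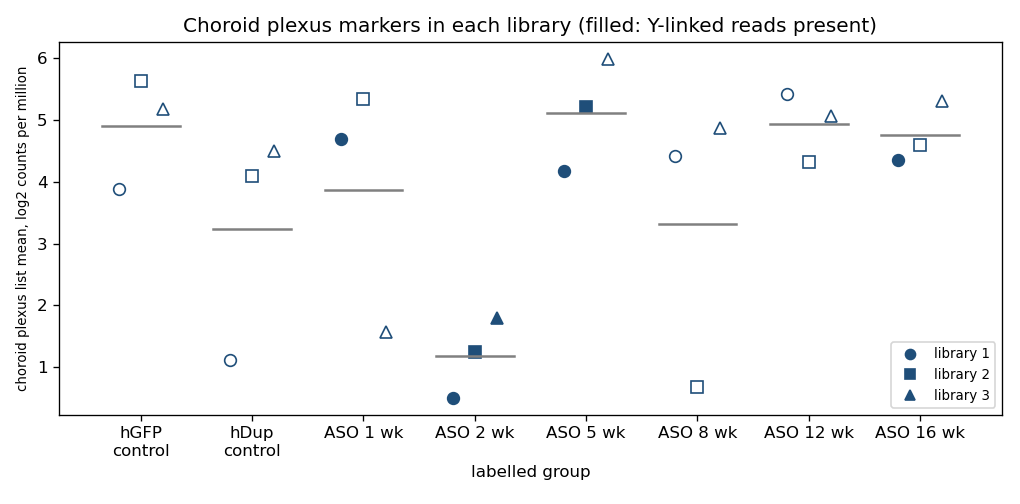
Mean log2 CPM of the 18 choroid plexus markers (vertical axis) for each library of the 8 labelled groups (horizontal axis), with filled points for libraries with Y-linked reads and lines for the group mean. Libraries labelled 2 weeks sit at 0.507 to 1.80, and hDup control library 1 (1.12), 1-week library 3 (1.57) and 8-week library 2 (0.68) sit as low.

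At 5 weeks choroid plexus markers were higher than in hDup control in all 18 (median 1.56, camera adjusted p = 1.04e-15; adjusted p = 0.764 with an estimated correlation). Kl, the membrane protein klotho, stood at 193 ± 96.7 against 74.3 ± 46.8 CPM (SD, n = 3 each). Genes of cholesterol synthesis were lower in all 19 (median −0.14, camera adjusted p = 6.86e-07; adjusted p = 0.677 with an estimated correlation), with Fdft1 at 63.4 ± 6.43 against 74.3 ± 6.56 CPM and Insig1, a sterol sensor, at 51.3 ± 6.31 against 59.8 ± 8.93. Both calls held without any 1 library, with a choroid plexus median of 0.995 without 5-week library 3 and a cholesterol median of −0.211 and −0.069 without hDup control library 2 and 3. Drd2, a dopamine receptor abundant in striatum, was the 1 marker of thalamus and striatum adjusted over the list alone (log2 fold change −0.80, SE 0.24, list adjusted p = 0.0449). Libraries 1 and 2 of this group had Y-linked reads.

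At 5 weeks against hDup control edgeR called 0 genes, 777 had an unadjusted p under 0.05 (1201 with the Y-linked term, 1327 without 5-week library 1), and DESeq2 called 0. Without 5-week library 1, edgeR called 1 gene, Emb, the adhesion protein embigin (log2 fold change 0.86). Libraries did not overlap for 9.78% of genes (10% by chance). The log2 fold change of human MECP2 was −0.65 (SE 0.46, adjusted p = 1) and that of mouse Mecp2 was 0.13 (SE 0.29). Camera called 10 lists, 6 higher and 4 lower, with 6 without hDup control library 3 and 5 without 5-week library 2.

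At 8 weeks mitochondrially encoded genes were higher than in hDup control in all 14 (median 0.40, camera adjusted p = 1.8e-08; adjusted p = 0.946 with an estimated correlation; 8 members adjusted over the list alone, 0 over all genes). Nuclear genes of oxidative phosphorylation were higher in 23 of 24 (median 0.22, camera adjusted p = 7.62e-09; adjusted p = 0.946 with an estimated correlation), and cytosolic ribosome genes in 27 of 32 (median 0.15, camera adjusted p = 0.000561; adjusted p = 0.946 with an estimated correlation). The SDs show how uneven the group was: mt-Co2, a subunit of complex IV, stood at 61.6 ± 55.0 against 28.0 ± 1.75 CPM (SD, n = 3 each). Without 8-week library 2 all 3 calls ended, with medians of 0.06, 0.002 and −0.05, and the ribosome call also ended without hDup control library 3 (0.12). Without 8-week library 1 or 3 the medians rose to 0.345 and 0.344 for oxidative phosphorylation and to 0.249 and 0.235 for ribosome genes. Lef1, a transcription factor of thalamic neurons, was adjusted over the list alone 1 of 18 thalamus and striatum markers past the threshold (log2 fold change 0.66, SE 0.19, list adjusted p = 0.0435).

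At 8 weeks against hDup control edgeR called 0 genes, 1550 had an unadjusted p under 0.05, and DESeq2 called 0. The number at an unadjusted p under 0.05 was 651 without 8-week library 2, 3391 without its library 1, 2620 without its library 3 and 420 in a fit of only these groups. Libraries did not overlap for 8.28% of genes (10% by chance). Human MECP2 had a log2 fold change of −0.13 (SE 0.45, adjusted p = 0.95), which turned without 8-week library 2 (0.26), hDup control library 1 (0.01) or hDup control library 3 (0.01), and mouse Mecp2 of 0.09 (SE 0.28; −0.02 without 8-week library 3). Camera called 3 lists, and 9, 6 and 7 without hDup control library 1, 2 and 3, 5 without 8-week library 2 5 without its library 3, 8 in a fit of only these groups and 5 with a choroid plexus term.

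At 12 weeks microglia markers were lower than in hDup control in 17 of 18 (median −0.17, camera adjusted p = 0.00113; adjusted p = 0.873 with an estimated correlation), among them Csf1r, the receptor that microglia need to survive (73.4 ± 5.58 against 85.5 ± 5.72 CPM, SD, n = 3 each), and Ctss, a lysosomal protease (45.3 ± 9.44 against 60.7 ± 8.84). Choroid plexus markers were higher in all 18 (median 1.247, camera adjusted p = 3.5e-12; adjusted p = 0.873 with an estimated correlation), with Aqp1, a water channel, at 22.04 ± 9.70 against 7.95 ± 6.40 CPM. Ependymal markers were higher in all 11 (median 0.43, camera adjusted p = 0.000585; adjusted p = 0.873 with an estimated correlation). These 3 calls held without any 1 library, but the choroid plexus median was 0.716 without hDup control library 1, and the microglia median was −0.079 without 12-week library 1 and −0.261 without its library 2. A choroid plexus term ended the ependymal call (median 0.12).

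At 12 weeks against hDup control edgeR called 0 genes, 655 had an unadjusted p under 0.05, and DESeq2 called 1. That gene was Ide (ENSMUSG00000056999.14), at 74.8 ± 4.08 against 47.5 ± 2.88 CPM (edgeR log2 fold change 0.65, SE 0.13, adjusted p = 0.983), which edgeR on only these groups also called (0.66). The number at an unadjusted p under 0.05 was 1012 without 8-week library 2, 297 without 12-week library 1, 1196 without its library 3, 1085 with a choroid plexus term and 1197 in a fit of only these groups. Libraries did not overlap for 11.97% of genes (10% by chance). For human MECP2 the log2 fold change was 0.06 (SE 0.45, adjusted p = 0.996), which turned without hDup control library 2 (−0.18), 12-week library 1 (−0.05) or 12-week library 3 (−0.09), and with a choroid plexus term (−0.19). Mouse Mecp2 had a log2 fold change of 0.21 (SE 0.28). Camera called 9 lists, 7 higher and 2 lower, and 15 without hDup control library 2.

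At 16 weeks the mouse gene Mecp2 itself (ENSMUSG00000031393.16, GRCm38 chromosome X, 74026592 to 74135363, minus strand) stood at 58.4 ± 31.6 against 17.9 ± 2.19 CPM in hDup control (SD, n = 3 each). Its libraries stood at 23.4, 84.9 and 66.9 CPM, and the other 21 libraries at 12.9 to 28.7. The log2 fold change was 1.70 (SE 0.28, edgeR adjusted p = 0.0595), just outside the threshold. DESeq2 called it (1.71, adjusted p = 0.000742), as did edgeR without 16-week library 1 (2.09, adjusted p = 5.75e-07) and edgeR with a Y-linked term (1.79, adjusted p = 0.0126). Library 1 had Y-linked reads and libraries 2 and 3 had none. Over all its alternatives the log2 fold change was positive. Irak1, the kinase gene next to it (chromosome X, 74013914 to 74023918), stood at 130, 92.0 and 99.8 CPM in the same libraries (log2 fold change −0.28, SE 0.10, adjusted p = 1) and was chosen after its values were seen. Choroid plexus markers were higher in all 18 (median 1.06, camera adjusted p = 2.02e-11; adjusted p = 0.963 with an estimated correlation), but not past the threshold without hDup control library 1 (0.53). That median was 1.633 without hDup control library 3 and 0.689 without 16-week library 3.

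For 16 weeks against hDup control edgeR called 0 genes, 417 had an unadjusted p under 0.05 (641 without 16-week library 1), and DESeq2 called 1, Mecp2. Non-overlap of the libraries held for 8.63% of genes (10% by chance). The log2 fold change of human MECP2 was 0.16 (SE 0.45, adjusted p = 1), which turned without hDup control library 2 (−0.08) or 16-week library 1 (−0.01), with a Y-linked term (−0.07) and with a choroid plexus term (−0.05). Camera called 4 lists, 2 higher and 2 lower, with 11 without hDup control library 2, 2 without its library 3 and 8 without 16-week library 1.

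**Figure D3:**
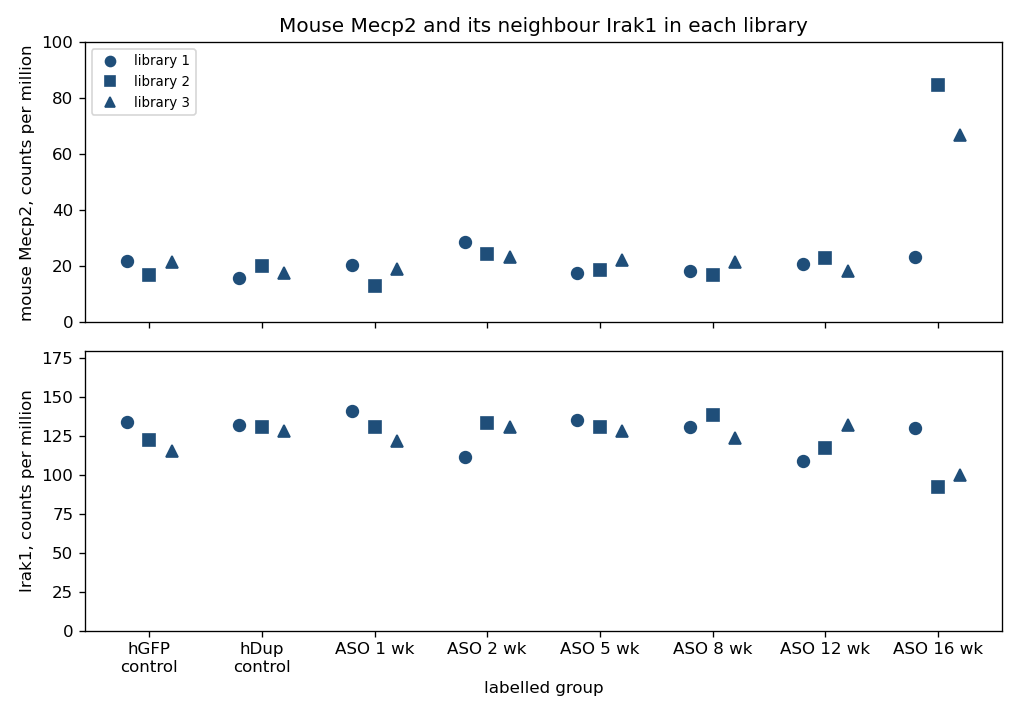
Mouse Mecp2 (upper panel) and Irak1 (lower panel) in CPM on the vertical axes for each library of the 8 labelled groups (horizontal axis), with a symbol per library number. Libraries 2 and 3 labelled 16 weeks hold 84.9 and 66.9 for Mecp2 and 92.0 and 99.8 for Irak1.

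Over the 6 times of MECP2 ASO, the 6 genes of smallest p were Mecp2, Capn6, Ide, Fap, Doc2b and Sox8. Mecp2 (F = 13.7, adjusted p = 0.0665) stood at 17.6, 25.5, 19.6, 18.95, 20.7 and 58.4 CPM in order of time. Capn6, a calpain-like protein without protease activity (F = 10.5, adjusted p = 0.261), stood at 1.195 CPM at 2 weeks and at 2.25 to 3.73 at the other times. Ide (adjusted p = 0.775) stood at 47.5, 49.6, 49.0, 63.9, 74.8 and 51.5 CPM, with 67.6 in hGFP control and 47.5 in hDup control. Fap, a protease of activated fibroblasts, stood at 0.508 CPM at 2 weeks, the group low in choroid plexus markers, and at 2.10 to 4.60 at the other times. Doc2b, a calcium sensor of vesicle release, was at 140 CPM at 2 weeks and at 93.6 to 115 otherwise, and Sox8, a transcription factor of glia, at 45.5 CPM at 2 weeks and at 49.7 to 60.5 otherwise (adjusted p = 0.775 for each of these 3). EdgeR called 0 genes over time, 1161 had an unadjusted p under 0.05 (957 by chance), and DESeq2 called 37. The number at an unadjusted p under 0.05 in edgeR was 668 with a Y-linked term, 2158 without 8-week library 1 and 1999 without its library 3. With the Y-linked term or without 16-week library 1 edgeR called 1 gene, Mecp2 (adjusted p = 0.0277 and 5.29e-07), and without 5-week library 1 it called 1, Emb (adjusted p = 0.0234). Time and age rise together in these groups. Libraries with and without Y-linked reads occur side by side at 1, 5 and 16 weeks, so the Y-linked term rests on these times.

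Whether a MECP2 ASO moves hippocampal expression against the genotype difference could be described only across genes. With 0 genes called between hDup control and hGFP control, 0 could be counted as moved in the opposite direction at any time (1 at 12 weeks, Ide, without hGFP control library 1). Pearson's r between the genotype fold changes and the fold changes against hDup control was −0.47, −0.11, −0.50, −0.55, −0.65 and −0.49 in order of time over 19140 genes. Simulated unchanged groups gave −0.51, −0.50, −0.49, −0.49, −0.51 and −0.51, since the hDup control libraries enter both sides. Without 1 library these r ran from −0.74 (8 weeks, without hDup control library 2) to −0.06 (2 weeks, without 2-week library 1). Later times against 1 week share no library with the genotype comparison, and there r was 0.25, −0.13, −0.12, −0.16 and −0.04 for 2, 5, 8, 12 and 16 weeks, with simulated values from −0.003 to 0.003 and SDs of 0.012 to 0.022. These values moved far more between alternatives than between simulations. At 2 weeks r was 0.0171 with no filter on low counts, 0.1052 with a Y-linked term, 0.0937 without hGFP control library 2, 0.1417 without hDup control library 1 and 0.1484 without 1-week library 2. With no filter r was −0.013 at 5 weeks and −0.0208 at 12 weeks, and it was also closer to 0 at 8 and 16 weeks. Without 1 library it ran from −0.1411 (1-week library 2) to 0.0452 (5-week library 3) at 5 weeks and from −0.3903 (1-week library 2) to −0.0188 (hGFP control library 3) at 8 weeks. At 12 weeks it ran from −0.1918 (1-week library 2) to −0.0028 (12-week library 1), and at 16 weeks from −0.0933 (1-week library 2) to 0.1141 (16-week library 3). The 16-week sign also turned without hDup control library 1 (9e-04), hDup control library 2 (0.0145) or 1-week library 1 (0.0442). For the 100 genes of smallest p in each direction of the genotype comparison, fry called 0 of 10 tests at later times against 1 week (smallest fry adjusted p = 0.214). Camera at its preset correlation called 4, which went different ways. The genes lower in hDup control had a median log2 fold change of −0.317 at 2 weeks (camera adjusted p = 1.24e-11) and of 0.076 at 5 weeks (camera adjusted p = 0.00637), and the genes higher in hDup control of −0.066 at 8 weeks (camera adjusted p = 0.00637) and −0.041 at 12 weeks (camera adjusted p = 0.0308).

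**Figure D4:**
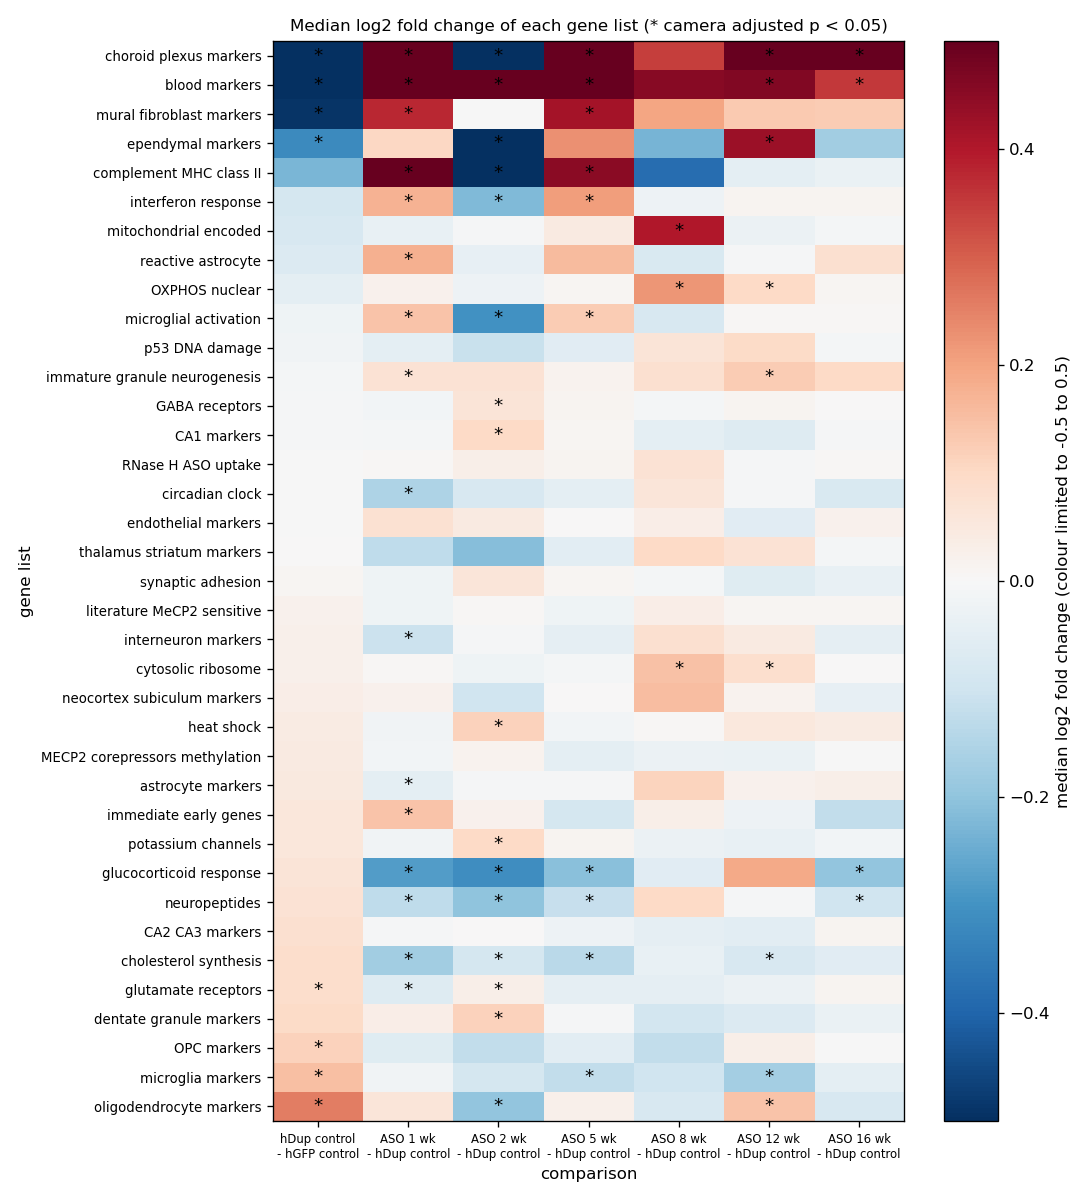
Median log2 fold change of each of the 37 gene lists (vertical axis) in hDup control against hGFP control and in each time against hDup control (horizontal axis), with colour limited to −0.5 to 0.5 and a star where the camera adjusted p was under 0.05. Medians of choroid plexus markers ran from −2.82 at 2 weeks to 1.56 at 5 weeks.

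Against hGFP control, the question is whether treated hDup mice differ from mice with 1 allele. At 1 week genes of the circadian clock were lower in 14 of 18 (median −0.15, camera adjusted p = 9.03e-05; adjusted p = 0.539 with an estimated correlation), and this was the 1 of 11 list calls (5 higher, 6 lower) that held without any 1 library (median −0.223 without hGFP control library 2 and −0.266 without 1-week library 1). Its members Cry1, a repressor of the clock (log2 fold change −0.37, SE 0.11), and Arntl, an activator of it (0.33, SE 0.14), went opposite ways. Irf7, a transcription factor of the interferon response, passed adjusted over the list alone (1.13, SE 0.32, list adjusted p = 0.0383). In edgeR 0 genes were called, 561 had an unadjusted p under 0.05, and DESeq2 called 1, Eif2s3y, present in the 1-week library with Y-linked reads. Without hGFP control library 1, edgeR called Ide (−0.71). The share of genes with no overlap was 8.65% (10% by chance). Human MECP2 had a log2 fold change of −0.34 (SE 0.46) and mouse Mecp2 of −0.20 (SE 0.28; 0.01 with a Y-linked term). Without 1-week library 2 the number of lists called was 5.

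At 2 weeks against hGFP control, choroid plexus markers were lower in all 18 (median −4.13, camera adjusted p = 8.29e-34; adjusted p = 0.114 with an estimated correlation), and all 18 passed adjusted over the list alone, 0 over all genes. Since these markers rise and fall together (median correlation 0.9735), the 18 are close to 1 measure per library. Ace, the angiotensin-converting enzyme, stood at 12.1 ± 2.15 against 73.1 ± 33.9 CPM (SD, n = 3 each). Ependymal markers were lower in all 11, of which 10 passed adjusted over the list alone (median −0.99, camera adjusted p = 2.16e-11; adjusted p = 0.114 with an estimated correlation). Genes of complement and MHC class II were lower in 9 of 10 (median −0.92, camera adjusted p = 0.00011; adjusted p = 0.22 with an estimated correlation), with 4 adjusted over the list alone: Serping1 and Cfh, which restrain complement, and H2-Aa and Cd74, of antigen presentation. Glutamate receptor genes were higher in 19 of 22 (median 0.14, camera adjusted p = 1.12e-05; adjusted p = 0.114 with an estimated correlation), with 3 adjusted over the list alone: Grm1 (log2 fold change 0.30, SE 0.09), Grin2a (0.32, SE 0.10) and Grin2b (0.27, SE 0.09). Dentate granule markers were higher in 13 of 14 (median 0.18, camera adjusted p = 6.29e-05; adjusted p = 0.22 with an estimated correlation), with Trpc6, Lct and Rasl10a adjusted over the list alone. Of the genes reported as sensitive to MeCP2, 4 of 27 passed adjusted over the list alone, Grin2a and Grin2b higher and Fxyd1 (−0.64, SE 0.19) and Igf2 (−1.56, SE 0.50) lower, while the list itself was not called. Members of other lists that passed in this way were Kcnq3, the heat shock gene Hsph1, the corepressor gene Ncor1, Spp1, Ogn and Igf2 of the mural cell and fibroblast markers, Ifi27 and H2-K1 of the interferon list, and Coch and Map3k15 of the CA2 and CA3 markers.

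All 3 libraries of the group labelled 2 weeks had Y-linked reads and no hGFP control library had. With a Y-linked term the complement (median −0.27) and dentate granule (0.05) calls ended, and a choroid plexus term ended the ependymal (−0.20), complement (−0.63) and glutamate receptor (0.11) calls. EdgeR called 0 genes, 1959 had an unadjusted p under 0.05 (536 with the Y-linked term), and DESeq2 called 159, edgeR on only these groups 306. Without hGFP control library 1 edgeR called 23 and without 8-week library 2 it called 72. Capn6 and Cdkn1c had the smallest adjusted p (0.0973 for each, log2 fold changes −1.51 and −1.66, SE 0.26 and 0.29). Ranges of the libraries were apart for 18.7% of genes (10% by chance). For human MECP2 the log2 fold change was 0.56 (SE 0.46, adjusted p = 0.731; −0.09 with the Y-linked term) and that of mouse Mecp2 was 0.35 (SE 0.28). Camera called 13 lists, 7 higher and 6 lower, of which 10 held without any 1 library.

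At 5 weeks against hGFP control, oligodendrocyte markers were higher in all 18 (median 0.23, camera adjusted p = 4.22e-07; adjusted p = 0.967 with an estimated correlation), which ended without hGFP control library 1 (0.09) and stood at 0.418, 0.151 and 0.129 without 5-week library 1, 2 and 3. At 8 weeks ependymal markers were lower in all 11 (median −0.59, camera adjusted p = 5.27e-08; adjusted p = 0.555 with an estimated correlation), among them Ccdc153 (2.37 ± 1.74 against 5.31 ± 0.902 CPM, SD, n = 3 each), and this call held without any 1 library (median −0.317 without hGFP control library 2, −0.30 without 8-week library 2 and −0.948 without 8-week library 3). Choroid plexus markers were lower at 8 weeks in all 18 (median −0.96, camera adjusted p = 1.32e-08; adjusted p = 0.555 with an estimated correlation), a call that ended without 8-week library 2 (−0.42), with −0.523 without hGFP control library 2 and −1.608 without 8-week library 3. Itgax, an integrin of activated microglia, passed at 8 weeks adjusted over the list alone (log2 fold change −2.28, SE 0.61, list adjusted p = 0.0181). EdgeR called 0 genes at each of these times, 550 (5 weeks) and 741 (8 weeks) had an unadjusted p under 0.05, and DESeq2 called 1 at each, Eif2s3y. That gene stood at 54.89 and 55.44 CPM in the 5-week libraries with Y-linked reads, but at 0.362 CPM or less in all 8-week libraries. Without 8-week library 2 the 5-week number was 874. The 8-week number was 1852 without 8-week library 1, 2181 without its library 3, 345 with a choroid plexus term and 267 in a fit of only these groups. Complete separation of libraries was seen for 8.98% and 6.14% of genes (10% by chance). Human MECP2 had log2 fold changes of −0.38 (SE 0.46) and 0.14 (SE 0.45), the latter negative without hGFP control library 1 (−0.27), 8-week library 1 (−0.08) or 8-week library 3 (−0.15). Mouse Mecp2 had −0.04 (SE 0.28; 0.03, 0.01 and 0.04 without hGFP control library 1, hGFP control library 3 and 5-week library 1, and 0.29 with a Y-linked term) and −0.08 (SE 0.28). Camera called 6 lists at 5 weeks (3 higher; 3 without hGFP control library 2) and 12 at 8 weeks (8 higher; 3 without 8-week library 2).

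At 12 weeks against hGFP control, oligodendrocyte lineage genes were higher. All 12 markers of oligodendrocyte precursors were higher (median 0.18, camera adjusted p = 2.75e-06), the 1 list call of all comparisons that held with an estimated correlation (adjusted p = 0.0474 with an estimated correlation; fry adjusted p = 0.355). Gpr17, a receptor of maturing precursors, stood at 51.3 ± 12.5 against 39.8 ± 1.90 CPM (SD, n = 3 each), and Olig2, a transcription factor of the lineage, at 32.7 ± 4.08 against 25.2 ± 3.68. Oligodendrocyte markers were higher in all 18 (median 0.40, camera adjusted p = 1.09e-22; adjusted p = 0.184 with an estimated correlation), with the myelin genes Mbp at 2384 ± 63.7 against 1775 ± 386 CPM, Plp1 at 1772 ± 155 against 1274 ± 319, Mal (log2 fold change 0.58, SE 0.19) and Cnp (0.43, SE 0.16). Mural cell and fibroblast markers were lower in 12 of 15 (median −0.29, camera adjusted p = 4.63e-05; adjusted p = 0.504 with an estimated correlation), and ribosome genes were higher in 31 of 32 (median 0.13, camera adjusted p = 4.13e-09; adjusted p = 0.504 with an estimated correlation). These 4 calls held without any 1 library, though the median of oligodendrocyte markers was 0.208 without hGFP control library 1. No member passed over all genes or adjusted over the list alone. By edgeR 0 genes were called, 385 had an unadjusted p under 0.05, and DESeq2 called 1, Eif2s3y, which stood at 0.057 CPM or less in these libraries. Groups stood fully apart for 7.38% of genes (10% by chance). The log2 fold change of human MECP2 was 0.33 (SE 0.45; −0.07 without hGFP control library 1) and that of mouse Mecp2 was 0.04 (SE 0.28; −0.07 without hGFP control library 2 and −0.03 without 12-week library 2). The mice labelled 12 weeks were 21 weeks old and those labelled hGFP control 10. Camera called 14 lists (8 higher), 9 without hGFP control library 2 and 6 without 12-week library 1.

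At 16 weeks against hGFP control, mouse Mecp2 stood at 58.4 ± 31.6 against 20.2 ± 2.71 CPM (SD, n = 3 each; log2 fold change 1.54, SE 0.27, edgeR adjusted p = 0.214). EdgeR called it without 16-week library 1 (1.92, adjusted p = 2.4e-06) and with a Y-linked term (1.62, adjusted p = 0.0452). Ependymal markers were lower in all 11 (median −0.49, camera adjusted p = 1.54e-05; adjusted p = 0.505 with an estimated correlation), the call of 9 (6 higher) that held without any 1 library (−0.236 without hGFP control library 2). Precursor markers of oligodendrocytes were higher in 11 of 12 (median 0.17, camera adjusted p = 4.35e-05; adjusted p = 0.0992 with an estimated correlation), which ended without hGFP control library 1 (0.094). Dpysl3, a protein of growing axons, was the 1 gene of immature granule neurons that passed adjusted over the list alone (log2 fold change 0.30, SE 0.07, list adjusted p = 0.00386). EdgeR called 0 genes, 539 had an unadjusted p under 0.05 (845 without 8-week library 2, 852 without 16-week library 3), and DESeq2 called 3: Mecp2, the phosphodiesterase gene Gdpd2 (log2 fold change 0.81) and Eif2s3y. Non-overlap of the libraries held for 8.82% of genes (10% by chance). Human MECP2 had a log2 fold change of 0.43 (SE 0.45, adjusted p = 0.999). Without hGFP control library 1 the number of lists called was 5.

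Long genes, which studies of MeCP2 often set apart, differed little from the rest. At 2 weeks against hDup control the median of genes longer than 100 kb lay 0.0364 log2 units above that of the others (camera adjusted p = 0.0127; adjusted p = 0.814 with an estimated correlation), and at 8 weeks −0.0433 (camera adjusted p = 0.0127; adjusted p = 0.814 with an estimated correlation). The 2-week call ended without hDup control library 1 (0.0268) or 2 (0.0279), or 2-week library 2 (0.0296) or 3 (0.0344), with no filter on low counts (0.015) and with a Y-linked term (4e-04). The 8-week call ended without hDup control library 3 (−0.0307) and with a cut of 200 kb (−0.0277, camera adjusted p = 0.0908), and the difference turned without 8-week library 2 (0.0131). With a cut of 50 kb the calls were those of 2 weeks (0.0347) and 8 weeks (−0.0514). Between hDup control and hGFP control the difference was 0.0146, and −0.0057 without hDup control library 3. The differences at 1, 5, 12 and 16 weeks were −0.0178, 0.0246, −0.02 and 0.0045. Of these, 1 week turned without 1-week library 2 (0.0018), 5 weeks was called without hDup control library 3 (0.0435) or 5-week library 2 (0.0321), with DESeq2 size factors or in DESeq2 (0.0244 for each), in a fit of only the groups compared (0.0252) and with a cut of 200 kb (0.0265, camera adjusted p = 0.048), and turned with a choroid plexus term (−0.0018), which led to a call at 12 weeks (−0.0385), and 16 weeks turned without hDup control library 1 (−0.0081) or 16-week library 1 (−0.017) and with a Y-linked (−0.0058) or choroid plexus term (−0.0182).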

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

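The tests of explanations for the 3 patterns below were chosen after the results were seen, as were the alternatives for which splits were refitted, while the other regroupings of libraries were planned beforehand.

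Library 1 labelled 2 weeks had the largest share of unmapped reads, 18.54% against at most 17.24% in a control library. Library 2 labelled 8 weeks had the largest share of reads with several alignments (4.757% against at most 4.005%), of reads outside genes (10.92% against at most 10.14%) and of reads at more than 1 gene (4.278% against at most 4.263%). The numbers of libraries above the highest control were 3, 1, 4 and 1 in that order.

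Human MECP2 reads did not follow the labelled groups. For mislabelled libraries, the between-group variance of log2 human MECP2 was no larger than random labels give (permutation p = 0.5276), which these libraries cannot separate from true differences between animals of 1 label. Sex of the animals as the whole cause is argued against by the hGFP control group, where no library had Y-linked reads and the highest was 3.93 times the lowest. Uneven action of the MECP2 ASO as the whole cause is argued against by the control groups as labelled, which had none and where that ratio was 1.884 (hDup) and 3.93 (hGFP). Within the treated groups such action stays open, since the ratio there reached 3.655 (8 weeks) and no value parts it from the spread seen in controls. Across filtered genes other than human MECP2, Y-linked genes, Xist and Tsix, libraries of 1 label correlated at −0.01201 on average, where random labels give −0.04144 (permutation p = 0.1363), and at −0.08797 after the trends with Y-linked reads and choroid plexus markers were removed (permutation p = 0.984), so this test leaves the labels undecided. Mixed-up labels, uneven transgene expression and the unstated assignment of human reads stay open.

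Choroid plexus markers were lower in the group labelled 2 weeks than in both control groups. Uneven carry-over of choroid plexus at dissection stays open. Libraries of the hDup control group spanned 3.391 log2 units, more than the −2.054 of the 2-week group from it, but those of the hGFP control group spanned 1.761, less than the −3.716 from that group. A lowering by the MECP2 ASO at every time is not decided. The list median lay above hDup control at 5 of 6 times and below hGFP control at 5 of 6. At 5 weeks it lay above both (1.564 and 0.219), by less than the libraries of each control group spanned (3.391 and 1.761). Library 1 of hDup control (1.118, others 4.096 and 4.508) lowers that group's mean. Sex of the animals as the whole cause is argued against for the difference from hGFP control: a term for Y-linked reads in the list mean left −3.501 log2 units (SE 1.548). For the difference from hDup control it left −1.839 (SE 1.548), so sex cannot be told apart there, because all 3 libraries of the 2-week group had such reads and few libraries of other groups did. In edgeR the list median with this term was −2.392 against hDup control and −3.648 against hGFP control, both still called by camera at its preset correlation.

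Mouse Mecp2 was higher in the 16-week group than in hDup control. The 16-week libraries held 439, 248 and 392 human and 23.4, 84.9 and 66.9 mouse CPM. This argues against a fixed share of human reads counted at the mouse gene. A varying share stays open (human log2 fold change 0.156). Animals that differ at the Mecp2 locus stay open, as the adjacent gene Irak1 (log2 fold change −0.282) was chosen after its values were seen. Age cannot be told apart from this, as the 12-week group had 0.207 (SE 0.28) and no group of 25 weeks had a control ASO. Library 1, of the same age, did not share the rise.

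Each comparison of 3 against 3 libraries was refitted with all 10 splits, which are too few for a share under 0.05. The labelled groups called 0 genes in each, so all 10 splits called as many by construction. The highest count of another split was 13 for 1 week against hDup control, 19 for 8 weeks against hGFP control, 1 for 12 weeks against each control, and 0 for the other 9 comparisons. In the alternatives refitted in this way, 2 weeks against hGFP control called 306 genes in a fit of only these groups (highest other split 0) and 778 with no filter on low counts (highest other 309). With no filter hDup control against hGFP control called 285, and another split called 300. For the time test the labelled times called 0 genes, so 100 of 100 regroupings (the labelled one included) called as many by construction, with 12 as the highest, which decides nothing about chance.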

How the results depend on the processing

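The Y-linked term, the choroid plexus term, the lists of 100 genes and the removal of 8-week library 2 from every comparison were chosen after the results were seen. EdgeR called 0 genes in each comparison, and the values given here are those that moved from that fit; the cause was not tested. Of the values of human MECP2 and mouse Mecp2 under the alternatives, 339 kept their direction and side of the threshold (26 of them with a minimum fold of 1.2, where this was fixed beforehand), 17 passed the threshold and 30 turned. Of list medians, 1467 kept both, 585 lost the call and 20 turned. DESeq2 size factors moved no count of called genes. A minimum fold of 1.2 is stricter than the test that called 0 genes, so its counts of 0 say nothing about stability. The long gene calls that moved are given above. Genes matched on expression change the long gene difference but not its test. Without a filter human MECP2 was called in comparisons whose libraries overlap. The stranded columns were not run. Replicate numbers did not pair the libraries: those of the same number in other groups correlated at 0.00547 on average (−0.25 to 0.27), and 12 of 24 libraries correlated best with their own number. The gene called with the replicate block was Zfp738 at 1 week against hGFP control (log2 fold change −1.03), chosen after its values were seen.

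Without a filter on low counts, the number of genes called was 285 (hDup control against hGFP control), 121 (1 week against hDup control), 316 (2 weeks against hDup control), 205 (5 weeks against hDup control), 310 (8 weeks against hDup control), 154 (12 weeks against hDup control) and 102 (16 weeks against hDup control). For others it was 152 (1 week against hGFP control), 778 (2 weeks against hGFP control), 100 (5 weeks against hGFP control), 152 (8 weeks against hGFP control), 72 (12 weeks against hGFP control), 116 (16 weeks against hGFP control) and 1192 (over time). The human MECP2 log2 fold change was −0.61 (1 week against hDup control), 0.28 (2 weeks against hDup control), −0.66 (5 weeks against hDup control), −0.34 (1 week against hGFP control), 0.54 (2 weeks against hGFP control), −0.40 (5 weeks against hGFP control) and 0.32 (12 weeks against hGFP control). For others it was 0.42 (16 weeks against hGFP control). The mouse Mecp2 log2 fold change was 0.51 (2 weeks against hDup control), 1.70 (16 weeks against hDup control) and 1.53 (16 weeks against hGFP control). The long gene difference was 0.015 (2 weeks against hDup control). The number of lists called was 2 (16 weeks against hDup control), 3 (5 weeks against hGFP control) and 9 (12 weeks against hGFP control). The number of opposite genes was 70 (1 week), 22 (2 weeks), 121 (5 weeks), 95 (8 weeks), 112 (12 weeks) and 77 (16 weeks). These share hDup control libraries with the genotype calls and have no chance level. R of genotype and ASO fold changes was −0.46 (2 weeks) and −0.51 (12 weeks). R of the genotype fold change with later times against 1 week was 0.017 (2 weeks), −0.013 (5 weeks) and −0.021 (12 weeks). Medians of genes higher in hDup control, at later times against 1 week, were −0.004 (16 weeks).

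With the Y-linked term, the mouse Mecp2 log2 fold change was 0.18 (1 week against hDup control), 1.79 (16 weeks against hDup control), 0.007 (1 week against hGFP control), 0.29 (5 weeks against hGFP control) and 1.62 (16 weeks against hGFP control). The human MECP2 log2 fold change was −0.36 (2 weeks against hDup control), −0.072 (16 weeks against hDup control) and −0.089 (2 weeks against hGFP control). Gene log2 fold changes were 0.034 (B2m in 2 weeks against hDup control). The number of genes called was 1 (16 weeks against hDup control), 1 (16 weeks against hGFP control) and 1 (over time). The number of lists called was 5 (2 weeks against hDup control). List medians were 0.068 (interferon response at 2 weeks against hDup control), −0.03 (glutamate receptors at 2 weeks against hDup control) and −0.026 (dentate granule at 5 weeks against hGFP control). The long gene difference was 0.0004 (2 weeks against hDup control) and −0.0058 (16 weeks against hDup control). R of genotype and ASO fold changes was −0.59 (1 week), −0.33 (2 weeks), −0.60 (5 weeks) and −0.60 (16 weeks). R of the genotype fold change with later times against 1 week was 0.11 (2 weeks), −0.22 (5 weeks) and −0.071 (12 weeks). Medians of genes higher in hDup control, at later times against 1 week, were −0.033 (2 weeks). Medians of genes lower in hDup control, at later times against 1 week, were −0.041 (12 weeks).

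In DESeq2, the number of genes called was 1 (hDup control against hGFP control), 2 (2 weeks against hDup control), 1 (12 weeks against hDup control), 1 (16 weeks against hDup control), 1 (1 week against hGFP control), 159 (2 weeks against hGFP control) and 1 (5 weeks against hGFP control). For others it was 1 (8 weeks against hGFP control), 1 (12 weeks against hGFP control), 3 (16 weeks against hGFP control) and 37 (over time). The mouse Mecp2 log2 fold change was 1.71 (16 weeks against hDup control) and 1.54 (16 weeks against hGFP control). The long gene difference was 0.024 (5 weeks against hDup control). R of genotype and ASO fold changes was −0.31 (1 week), 0.0016 (2 weeks), −0.34 (5 weeks) and −0.33 (16 weeks). R of the genotype fold change with later times against 1 week was −0.33 (12 weeks). Medians of genes lower in hDup control, at later times against 1 week, were 0.005 (16 weeks).

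With the choroid plexus term, gene log2 fold changes were 0.034 (Rsph1 in hDup control against hGFP control), 0.012 (Dynlrb2 in hDup control against hGFP control), 0.12 (Tlr2 in 2 weeks against hGFP control) and 0.058 (Bst2 in 2 weeks against hGFP control). The human MECP2 log2 fold change was −0.19 (12 weeks against hDup control) and −0.054 (16 weeks against hDup control). List medians were 0.012 (ependymal at hDup control against hGFP control). The long gene difference was −0.0018 (5 weeks against hDup control), −0.038 (12 weeks against hDup control) and −0.018 (16 weeks against hDup control). The number of lists called was 5 (8 weeks against hDup control). Medians of genes lower in hDup control, at later times against 1 week, were 0.029 (8 weeks) and −0.048 (12 weeks). R of the genotype fold change with later times against 1 week was −0.23 (12 weeks) and −0.13 (16 weeks). Medians of genes higher in hDup control, at later times against 1 week, were −0.003 (16 weeks).

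In a fit of only the groups compared, the number of genes called was 10 (2 weeks against hDup control), 1 (12 weeks against hDup control) and 306 (2 weeks against hGFP control). The long gene difference was 0.025 (5 weeks against hDup control). The number of lists called was 8 (8 weeks against hDup control). R of genotype and ASO fold changes was −0.56 (1 week) and −0.61 (5 weeks).

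With a term for the replicate number, the number of genes called was 1 (1 week against hGFP control). The human MECP2 log2 fold change was −0.041 (8 weeks against hGFP control). Medians of genes lower in hDup control, at later times against 1 week, were 0.001 (16 weeks).

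With DESeq2 size factors, the long gene difference was 0.024 (5 weeks against hDup control).

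With long genes of over 200 kb, the long gene difference was 0.026 (5 weeks against hDup control) and −0.028 (8 weeks against hDup control).

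By camera with an estimated correlation, the number of lists called was 0 (hDup control against hGFP control), 0 (1 week against hDup control), 0 (2 weeks against hDup control), 0 (5 weeks against hDup control), 0 (8 weeks against hDup control), 0 (12 weeks against hDup control) and 0 (16 weeks against hDup control). For others it was 0 (1 week against hGFP control), 0 (2 weeks against hGFP control), 0 (5 weeks against hGFP control), 0 (8 weeks against hGFP control), 1 (12 weeks against hGFP control) and 0 (16 weeks against hGFP control).

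By fry, the number of lists called was 0 (hDup control against hGFP control), 0 (1 week against hDup control), 0 (2 weeks against hDup control), 0 (5 weeks against hDup control), 0 (8 weeks against hDup control), 0 (12 weeks against hDup control) and 0 (16 weeks against hDup control). For others it was 0 (1 week against hGFP control), 0 (2 weeks against hGFP control), 0 (5 weeks against hGFP control), 0 (8 weeks against hGFP control), 0 (12 weeks against hGFP control) and 0 (16 weeks against hGFP control).

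With 1 library left out, values ran from the lowest to the highest given here. The number of genes called ran from 0 to 1 (hDup control against hGFP control), 0 to 1 (5 weeks against hDup control), 0 to 1 (16 weeks against hDup control), 0 to 1 (1 week against hGFP control) and 0 to 72 (2 weeks against hGFP control). Further ranges were 0 to 1 (16 weeks against hGFP control) and 0 to 1 (over time). The human MECP2 log2 fold change ran from −0.13 to 0.60 (hDup control against hGFP control), −0.41 to 0.26 (8 weeks against hDup control), −0.18 to 0.30 (12 weeks against hDup control), −0.081 to 0.36 (16 weeks against hDup control) and −0.27 to 0.53 (8 weeks against hGFP control). Further ranges were −0.072 to 0.66 (12 weeks against hGFP control). The mouse Mecp2 log2 fold change ran from −0.15 to 0.16 (1 week against hDup control), −0.02 to 0.19 (8 weeks against hDup control), 1.34 to 2.09 (16 weeks against hDup control), −0.15 to 0.036 (5 weeks against hGFP control) and −0.068 to 0.12 (12 weeks against hGFP control). Further ranges were 1.16 to 1.92 (16 weeks against hGFP control). Gene log2 fold changes ran from −0.048 to 2.35 (mt-Nd3 in 8 weeks against hDup control), −1.07 to 0.029 (Cartpt in 16 weeks against hDup control), −0.073 to 0.39 (Cck in 8 weeks against hGFP control), −0.04 to 0.37 (Sst in 8 weeks against hGFP control) and −0.019 to 0.35 (Ntsr2 in 8 weeks against hGFP control). Further ranges were −0.046 to 0.39 (S100b in 8 weeks against hGFP control), −1.21 to 0.076 (H2-Ab1 in 8 weeks against hGFP control), −0.14 to 1.51 (Rspo1 in 8 weeks against hGFP control), −0.015 to 0.51 (mt-Nd6 in 8 weeks against hGFP control) and −0.005 to 0.48 (mt-Rnr2 in 8 weeks against hGFP control). Further ranges were −0.007 to 0.48 (Rps8 in 8 weeks against hGFP control), −0.006 to 0.41 (Rps29 in 8 weeks against hGFP control), −0.13 to 0.59 (Ndufb9 in 8 weeks against hGFP control), −0.46 to 0.044 (Ciita in 12 weeks against hGFP control) and −1.88 to 0.092 (mt-Nd4l in 12 weeks against hGFP control). The number of lists called ran from 4 to 14 (hDup control against hGFP control), 7 to 18 (1 week against hDup control), 9 to 19 (2 weeks against hDup control), 5 to 10 (5 weeks against hDup control) and 3 to 9 (8 weeks against hDup control). Further ranges were 6 to 15 (12 weeks against hDup control), 2 to 11 (16 weeks against hDup control), 5 to 14 (1 week against hGFP control), 3 to 9 (5 weeks against hGFP control) and 3 to 14 (8 weeks against hGFP control). Further ranges were 6 to 16 (12 weeks against hGFP control) and 5 to 10 (16 weeks against hGFP control). The long gene difference ran from −0.0057 to 0.029 (hDup control against hGFP control), −0.034 to 0.0018 (1 week against hDup control), 0.027 to 0.055 (2 weeks against hDup control), 0.011 to 0.043 (5 weeks against hDup control) and −0.085 to 0.013 (8 weeks against hDup control). Further ranges were −0.017 to 0.026 (16 weeks against hDup control). List medians ran from −0.01 to 0.082 (glutamate receptors at 2 weeks against hDup control), −0.047 to 0.25 (cytosolic ribosome at 8 weeks against hDup control), −0.056 to 0.29 (oligodendrocyte at 12 weeks against hDup control), −0.052 to 0.14 (OPC at 1 week against hGFP control) and −0.013 to 0.26 (immediate early genes at 2 weeks against hGFP control). Further ranges were −0.002 to 0.15 (interneuron at 8 weeks against hGFP control), −0.007 to 0.21 (microglia at 8 weeks against hGFP control), −0.031 to 0.26 (oligodendrocyte at 8 weeks against hGFP control), −0.019 to 0.47 (mitochondrial encoded at 8 weeks against hGFP control) and −0.023 to 0.26 (cytosolic ribosome at 8 weeks against hGFP control). Further ranges were −0.068 to 0.30 (OXPHOS nuclear at 8 weeks against hGFP control), −0.45 to 0.066 (complement MHC class II at 12 weeks against hGFP control), −0.002 to 0.075 (OXPHOS nuclear at 12 weeks against hGFP control), −0.046 to 0.24 (microglia at 16 weeks against hGFP control) and −0.58 to 0.043 (mural fibroblast at 16 weeks against hGFP control). R of genotype and ASO fold changes ran from −0.57 to −0.32 (1 week), −0.30 to −0.063 (2 weeks), −0.55 to −0.31 (5 weeks), −0.74 to −0.42 (8 weeks) and −0.67 to −0.42 (12 weeks). Further ranges were −0.56 to −0.29 (16 weeks). The number of opposite genes ran from 0 to 1 (12 weeks). R of the genotype fold change with later times against 1 week ran from 0.094 to 0.26 (2 weeks), −0.14 to 0.045 (5 weeks), −0.39 to −0.019 (8 weeks), −0.19 to −0.0028 (12 weeks) and −0.093 to 0.11 (16 weeks). Medians of genes higher in hDup control, at later times against 1 week, ran from −0.006 to 0.053 (2 weeks), −0.03 to 0.014 (5 weeks) and −0.022 to 0.018 (16 weeks). Medians of genes lower in hDup control, at later times against 1 week, ran from −0.055 to 0.17 (8 weeks), −0.068 to 0.16 (12 weeks) and −0.13 to 0.12 (16 weeks).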

Other observations

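The hypotheses on replicate numbers below were chosen after the results were seen.

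Of the 131 list calls by camera at its preset correlation, 1 held with an estimated correlation. When 1 library was left out, 101 of the 131 ended or turned. Those that held without each library were 5 calls of choroid plexus markers, 5 of ependymal markers, 4 of mural cell and fibroblast markers, 2 of cholesterol genes, 2 of potassium channel genes, and 1 each of oligodendrocyte markers, their precursor markers, dentate granule markers, microglia markers, microglial activation, interferon, complement and MHC class II, heat shock, ribosome, glutamate receptor and clock genes, and blood markers. Over the 13 comparisons, oligodendrocyte markers were called in 8 (7 higher) with medians from −0.20 to 0.40, and choroid plexus markers in 9 (4 higher) with medians from −4.13 to 1.56. Genes of the glucocorticoid response were called in 7 (6 lower, −0.31 to 0.19). Complement and MHC class II genes (−0.92 to 0.53), blood markers (−0.77 to 0.86), mural cell and fibroblast markers (−0.51 to 0.42), ependymal markers (−0.99 to 0.43) and cholesterol genes (−0.17 to 0.086, all lower) were called in 6 each. Microglia markers (−0.17 to 0.15), interferon genes (−0.32 to 0.21), precursor markers of oligodendrocytes (−0.13 to 0.18, all higher) and glutamate receptor genes (−0.064 to 0.14) were called in 5 each.

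Called in 4 each were dentate granule markers (−0.09 to 0.18), microglial activation genes (−0.36 to 0.14), neuropeptide genes (−0.20 to 0.15), heat shock genes (−0.018 to 0.15), mitochondrially encoded genes (−0.081 to 0.40), ribosome genes (−0.023 to 0.16) and oxidative phosphorylation genes (−0.075 to 0.22). Called in 3 each were interneuron markers (−0.11 to 0.085), genes of immature granule neurons (−0.009 to 0.19), astrocyte markers (−0.047 to 0.11), reactive astrocyte genes (−0.24 to 0.18), immediate early genes (−0.12 to 0.19) and clock genes (−0.16 to 0.06). GABA receptor genes (−0.012 to 0.095) and potassium channel genes (−0.038 to 0.17) were called in 2. CA1 markers (−0.12 to 0.10), endothelial markers (−0.11 to 0.077), markers of thalamus and striatum (−0.21 to 0.099), markers of neocortex and subiculum (−0.12 to 0.19), synaptic adhesion genes (−0.06 to 0.062), p53 targets (−0.11 to 0.095) and corepressors of MECP2 (−0.047 to 0.049) were called in 1. Genes reported as sensitive to MeCP2 (−0.022 to 0.064), CA2 and CA3 markers (−0.088 to 0.082) and genes of RNase H and ASO uptake (−0.037 to 0.074) were called in 0.

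Whether lists differ between times was tested over all 15 pairs of times, and 0 of 555 tests had an adjusted p under 0.05 (smallest fry adjusted p = 0.386).

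A candidate explanation of the spread in human MECP2 is that the replicate number carries a property of the libraries. Number 2 was lowest in 6 of 8 groups and lay −0.468 log2 units from the others (permutation p = 0.119). Over the 37 lists, the smallest adjusted permutation p was 0.07918, for precursor markers of oligodendrocytes, and 0 lists had one under 0.05. These tests do not separate such a property from differences between the animals.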
